A study of Mus musculus with 28 samples.

How the data were processed

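Total RNA of liver, quadriceps, heart and gastrocnemius from female mice aged 6 or 24 months was hybridised to Affymetrix expression arrays after amplification with a whole-transcript kit, per the labels' protocols. Liver and quadriceps (3 arrays per age each) share one array type and heart and gastrocnemius (4 arrays per age each) another, 28 arrays in all. The authors deposited log2 expression values with 2 decimals, 1 per probe set and array, in 2 tables, 1 per array type. RMA, which corrects background, normalizes arrays to each other and summarises probes, is named in the submitters' processing notes; its version is not given in the sources used here. Because such values are already normalized between arrays, a shift common to most genes of an array can be removed from them, and which arrays were normalized together is not given in the sources used here. The deposited arrays still differ in their interquartile range (2.43 to 2.79 over the liver arrays), so they do not share 1 distribution. Every column was matched to a sample by its name, with 0 columns left unmapped and no missing value.

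The liver and quadriceps table holds 28944 probe sets, of which 21797 have 1 gene symbol, 1613 several and 5534 none in the platform annotation. The heart and gastrocnemius table holds 65956, of which 30604 have 1, 2146 several and 33206 none. Symbols were updated through a RefSeq gene table of assembly GRCm38.p6, used for names only, which changed 23 and 1135 probe sets' symbols. Probe sets with several symbols or none stayed out of the tests of genes. Each gene was represented by its probe set with the highest mean over all arrays of the type, leaving 19928 and 30063 genes, 18974 of them measured in all 4 tissues. No genome position is reported, since no genome was given.

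Groups came from the labels. The design, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined; those added later are named as such. Per tissue, 24 months was compared with 6 months in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided), each tissue with its own estimate of spread, with Benjamini-Hochberg adjustment over all its genes and a threshold of 0.05. The differences between tissues of one array type were tested as an interaction term in a model of both tissues. Camera, which asks whether a list's genes rank higher or lower than other genes, was run with a preset correlation of 0.01 between genes on the lists, out of 52 fixed, that apply to the tissue and have at least 5 measured members, with adjustment over the lists of that tissue. Members were also adjusted over their list alone. Camera was repeated with an estimated correlation, and fry was run, which tests whether a list's genes move one way without comparing them with other genes. Shared genes of the 6 tissue pairs were tested per direction with Fisher's exact test, one-sided, adjusted over the pairs and directions. To see whether a list stood apart from genes of like expression, its median was set against the middle 95% of 10000 random lists matched on mean expression in 20 bins.

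Genes named in the text are the 8 with the largest change in each direction among those past the threshold, filled to 5 per direction with those of smallest p where fewer passed, the 3 members of smallest p of each list past its threshold (4 for the atrial markers), the 5 of smallest p per tissue difference, and 2 senescence markers in every tissue where they were measured; genes named to describe single arrays or another list's members were chosen after their values were seen.

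The alternatives were quantile normalization, arrays centred on their median, dim genes left out (neither age's mean at the median of all values or above), every probe set tested, an intensity trend with a robust prior, a fit joint with the other tissue of the table, array weights, the replicate number as a block, a minimum of 1.5-fold and leaving out each array in turn. Cyclic loess normalization with 3 iterations, the mean of the atrial markers as a covariate in heart and the count of genes moving alike in all 4 tissues were chosen after seeing the data. Counts of calls were also taken over at most 100 other splits of the arrays. The fits were tested on simulated data with 200 changed genes, 100 of them by 1 log2 unit, at the real spread: 99, 99, 100 and 100 of the latter were recovered in liver, quadriceps, heart and gastrocnemius (among 19928 or 30063 genes), 96 and 97 in the 2 tissue differences. Unchanged genes called were 15, 15, 11 and 14 in the tissues and 9 and 13 in the differences. A list of 20 genes moved by 0.3 was recovered with 0 other lists called. The simulated genes varied independently, so this could not show false list calls that arise where genes vary together. In the real arrays other splits gave up to 21, 18, 10 and 22 lists in liver, quadriceps, heart and gastrocnemius. Pairs of arrays were compared for duplicates and none were found. Depth has no counterpart on arrays, and the number of arrays per group sets the precision.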

Results

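Gene expression was measured in 28 samples of total RNA from female C57BL/6J mice, an inbred laboratory strain kept in groups on chow, at 6 or 24 months of age (24 or 103 weeks) and after a night without food. The stated aim was to profile transcripts of metabolic tissues in young and old animals. Liver and the quadriceps, a thigh muscle, had 3 arrays per age. The heart and the gastrocnemius, a calf muscle, had 4 arrays per age on a second array type. The deposited values are log2 expression, so a difference of 1 is a 2-fold difference. The 4 tissues carried their usual transcripts: Alb, which encodes serum albumin, lay between 14.09 and 14.16 in the liver arrays. Myh4, a fast myosin heavy chain, lay between 13.70 and 13.83 in quadriceps and between 13.55 and 13.62 in gastrocnemius, and Myh6, the adult cardiac myosin heavy chain, between 13.16 and 13.29 in heart. Array medians ran from 6.47 to 6.62 in liver, from 6.36 to 6.40 in quadriceps, from 5.27 to 5.35 in heart and from 4.88 to 4.97 in gastrocnemius. The lowest Pearson r between arrays of one tissue, taken across genes, which are not independent replicates, was about 0.985, 0.992, 0.995 and 0.993. The number of arrays limits the precision: the median standard error of an age difference was 0.10, 0.08, 0.06 and 0.07 log2 units in these 4 tissues. The labels do not say whether the arrays of one group came from separate animals or whether tissues were taken from the same animals, so p-values measure the spread between these samples.

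The first comparison asked which liver transcripts differed between 24 and 6 months. Cyp2b9, a cytochrome P450 expressed more strongly in female liver, rose 19.0-fold, from 5.44 ± 0.52 to 9.69 ± 1.56 (SD, n = 3 per age, log2 difference 4.25, SE 0.64). The difference was 5.13 without 24-month replicate 2 and 3.66 without 24-month replicate 3, or 35.1-fold and 12.6-fold. At 6 months Cyp2b9 lay between 5.06 and 6.04, below the median of each 6-month array (6.47 or 6.48). The fold thus starts from a low value that was not shown to exceed background. Gpx6, a glutathione peroxidase, rose 2.27-fold from 6.15 ± 0.14 to 7.33 ± 0.41, and Noct, which encodes nocturnin and follows a daily rhythm in liver, rose 1.96-fold from 7.98 ± 0.20 to 8.95 ± 0.04. Cdh1, which encodes the epithelial adhesion protein E-cadherin, fell by 1.22 on the log2 scale, from 8.64 ± 0.31 to 7.42 ± 0.20. Cyp4a12b, a fatty acid hydroxylase expressed more strongly in male liver, fell by 0.90 from 12.44 ± 0.10 to 11.54 ± 0.15, and Il1a, the cytokine interleukin-1 alpha, fell by 0.87 from 7.67 ± 0.16 to 6.80 ± 0.23.

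Among liver genes past the threshold, the other largest rises were in Dmrta1 (1.14), the protocadherin gene Pcdh11x (0.97), the immunoglobulin segment Igkv10-96 (0.91), the organic anion transporter gene Slc22a26 (0.76) and Raet1d (0.70), whose product is a ligand of a natural killer cell receptor. The other large falls among them were in Rarres1 (-1.07), Nat8f5 (-1.05), Sel1l3 (-0.92), Uprt (-0.91) and Tmem62 (-0.89). In all, limma called 65 of 19928 genes at an adjusted p under 0.05, 28 higher and 37 lower, each at an adjusted p of 0.0493, and in all 65 the 3 arrays of one age lay wholly above the 3 of the other, which chance gives for 10% of all genes but which a choice by small p favours, so that it is no separate evidence. At an unadjusted p under 0.05 there were 6529 genes, where 996 would be expected by chance. The count depended on single arrays: it was 12 without 6-month replicate 1, 0 without 6-month replicate 2 or replicate 3, 1 without 24-month replicate 1 or replicate 2, and 5073 without 24-month replicate 3, and no liver gene named here kept its call in all 6 of these fits. The age difference also followed expression level across genes (Spearman rho -0.45, where genes are not independent replicates): with genes parted into 10 equal classes by expression, its median was 0.18 in class 4 and -0.14 in classes 8 and 9. Against the mean of the 6-month arrays rho was -0.476, -0.454 and -0.215 in 24-month replicates 1, 2 and 3, and replicate 3 had a higher mean Pearson r with the 6-month arrays (0.994) than with its own group (0.992). The interquartile range was 2.75, 2.79 and 2.79 in the 6-month arrays and narrower, at 2.43, 2.49 and 2.66, in 24-month replicates 1, 2 and 3. Centring each array on its median moved the median difference of all genes from 0.03 to -0.09 and the split of calls to 355 higher and 2515 lower.

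**Figure D1:**
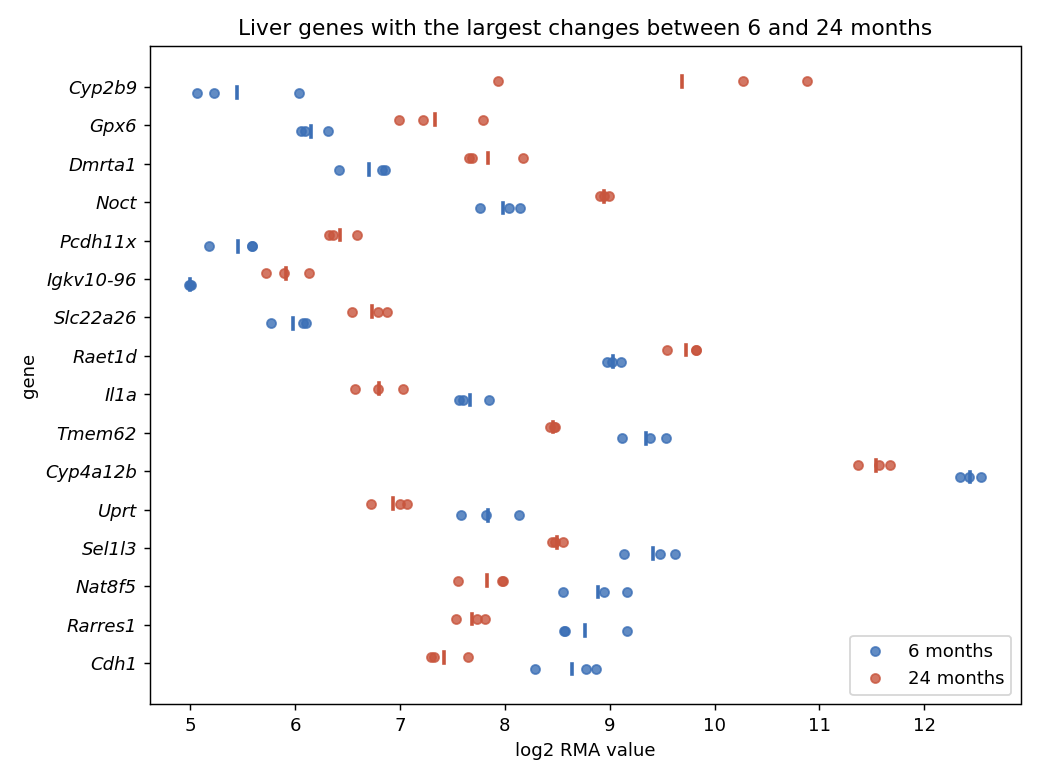
Log2 expression (horizontal axis) of the 16 liver genes with the largest changes past the threshold, 8 higher and 8 lower at 24 months, with 1 point per array (3 per age) and a bar at each group mean. The 3 arrays of one age lie wholly above the 3 of the other in each gene, with Cyp2b9 at 10.27, 7.93 and 10.88 at 24 months against 6.04, 5.23 and 5.06 at 6 months.

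Liver genes that differ between the sexes moved in opposite directions, as lists fixed in advance. At 6 months the male-biased Cyp4a12b stood at 12.44 and the female-biased Cyp2b9 at 5.44, although the mice are described as female. The stated sex was not checked with a sex-linked gene, so whether it holds for every sample was not tested. The male-biased list fell (median log2 difference -0.35, camera, adjusted p = 1.04e-08): 22 of 24 members were lower and 3 of them, Cyp4a12b, Cyp4a12a (-0.72) and the peroxisomal hydrolase gene Nudt7 (-0.77), passed over all genes, and 15 fell adjusted over the list alone. Its adjusted p = 0.437 with an estimated correlation. The female-biased list rose (0.34, adjusted p = 0.0135): 3 of 21 members rose over all genes, namely Cyp2b9, Slc22a26 and the related transporter gene Slc22a27 (0.62), and 7 rose adjusted over the list alone. This list had adjusted p = 0.576 with an estimated correlation and did not pass without 24-month replicate 3 (median 0.16, adjusted p = 0.181). Genes of xenobiotic metabolism, which handle drugs and foreign compounds, also rose (0.18, adjusted p = 0.00735), with no member of 29 past over all genes and 9 higher adjusted over the list alone, among them Cyp2b10 (0.73), Ahr (0.58) and Cyp2c38 (0.84). For this list adjusted p = 0.648 with an estimated correlation, and 0.133 with the preset one without 24-month replicate 3.

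Protein folding genes fell in liver. Of 20 heat shock genes, whose products are chaperones, 1 passed over all genes (Hsp90aa1, which fell by 0.75), and 14 fell and 2 rose adjusted over the list alone (median -0.44, adjusted p = 1.01e-05, and adjusted p = 0.553 with an estimated correlation). Other members were Hsph1 (-0.85) and Chordc1 (-0.81). Hspa1a, an inducible chaperone gene, stood at 8.64 in 6-month replicate 3 and between 6.42 and 7.21 in the other liver arrays. Of 28 genes of endoplasmic reticulum stress and the integrated stress response, 1 fell over all genes (the disulphide isomerase gene Pdia6, -0.48), and 15 fell and 2 rose adjusted over the list alone, with Hspa5 at -0.44 and Hyou1 at -0.46 (median -0.24, adjusted p = 0.000116, and adjusted p = 0.437 with an estimated correlation). Its median was -0.15 with cyclic loess, chosen after seeing the data. Autophagy genes fell (median -0.11, adjusted p = 0.000996): none of 24 members passed over all genes and 1 fell adjusted over the list alone, with Wipi1 at -0.44, Atg13 at -0.25 and Atg4b at -0.28 (adjusted p = 0.576 with an estimated correlation).

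Lists of mitochondrial and fat-burning genes fell in liver, with no member past the threshold over all genes. Of 72 nuclear-encoded genes of oxidative phosphorylation, the respiratory chain and ATP synthase, 63 were lower (median -0.11, adjusted p = 3.14e-06), with Ndufa1 at -0.51, Atp5l at -0.33 and Atp5k at -0.29. None fell adjusted over the list alone. The list had adjusted p = 0.437 with an estimated correlation. The tricarboxylic acid cycle list fell (-0.16, adjusted p = 8.91e-05), with 8 of 21 members lower adjusted over the list alone, such as Pdhb (-0.52) and Dlst (-0.34). These genes had adjusted p = 0.437 with an estimated correlation. Fatty acid oxidation genes fell (-0.11, adjusted p = 0.00735, 1 of 25 lower adjusted over the list alone), as did the PPAR-driven fasting and ketogenesis genes (-0.14, adjusted p = 0.00351, 2 of 17 lower adjusted over the list alone), both lists holding Ehhadh (-0.47), a peroxisomal oxidation enzyme gene. For each of these 2 lists adjusted p = 0.576 with an estimated correlation. Regulators of mitochondrial biogenesis fell (-0.16, adjusted p = 0.0197, 4 of 16 lower adjusted over the list alone), among them Tfam (-0.44) and Tfb1m (-0.52), which act in mitochondrial transcription, with adjusted p = 0.553 with an estimated correlation, and their median was -0.10 without 24-month replicate 1. These lists lie in the upper range of expression, where the median gene was also lower at 24 months. Quantile normalization and leaving out dim genes each ended the calls of fatty acid oxidation, PPAR, mitochondrial biogenesis and autophagy, and cyclic loess, chosen after seeing the data, ended those of oxidative phosphorylation (adjusted p = 0.0671), fatty acid oxidation, mitochondrial biogenesis and autophagy. With quantile normalization and with cyclic loess the medians were -0.06 and -0.05 for oxidative phosphorylation, -0.07 and -0.06 for the tricarboxylic acid cycle, -0.07 and -0.05 for fatty acid oxidation, -0.06 and -0.07 for PPAR, -0.04 and -0.05 for mitochondrial biogenesis and -0.03 and -0.02 for autophagy.

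Immune cell markers rose in liver, with no member past over all genes. T and NK cell markers rose (median 0.24, adjusted p = 0.000644, 3 of 24 higher adjusted over the list alone), with Cd5 at 0.55 and Cd2 at 0.51. B and plasma cell markers rose (0.31, adjusted p = 0.00107, 4 of 17 higher adjusted over the list alone), with the antibody joining chain gene Jchain at 0.98, Igha at 0.82 and Ighm at 0.49. For both lists adjusted p = 0.576 with an estimated correlation. Neutrophil markers rose (0.27, adjusted p = 0.00254, 5 of 18 higher adjusted over the list alone), with Mpo at 0.46 and S100a9 at 0.40. This list gave adjusted p = 0.553 with an estimated correlation. Macrophage markers rose (0.12, adjusted p = 0.0313, none of 30 adjusted over the list alone, Gpnmb 0.32). These genes had adjusted p = 0.722 with an estimated correlation and did not pass without 6-month replicate 2 (adjusted p = 0.0505), 24-month replicate 1 (median 0.06, 0.306) or 24-month replicate 2 (0.0545). MHC class II genes, which present antigen, rose (0.17, adjusted p = 0.0441, 2 of 11 higher adjusted over the list alone, H2-DMa 0.34). These genes had adjusted p = 0.708 with an estimated correlation and did not pass without 6-month replicate 2 (adjusted p = 0.0713), 6-month replicate 3 (0.0881) or 24-month replicate 1 (median 0.08, 0.306). Without 24-month replicate 1 the medians of the T and NK, B and plasma cell and neutrophil lists were 0.16, 0.19 and 0.14, and without 24-month replicate 3 that of macrophage markers was 0.21. With quantile normalization and with cyclic loess the medians were 0.11 and 0.10 for T and NK cells, 0.16 and 0.15 for neutrophils and 0.20 and 0.18 for macrophages.

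Markers of other tissue and stromal cells rose alongside. Adipocyte markers rose (median 0.24, adjusted p = 0.00810), with no member past over all genes and 8 of 19 higher and 1 lower adjusted over the list alone: Cidea, a lipid droplet gene, differed by 1.68, Trarg1 by 0.51 and Plin4 by 0.43. Schwann cell and myelin markers rose (0.22, adjusted p = 0.00176, none of 18 adjusted over the list alone, Cdh19 0.52, Sox10 0.30). For both lists adjusted p = 0.471 with an estimated correlation. Fibroblast markers rose (0.19, adjusted p = 0.0162, 4 of 23 higher and 1 lower adjusted over the list alone, Col1a1 0.39, adjusted p = 0.576 with an estimated correlation), but not without 6-month replicate 1 (adjusted p = 0.102), and the median was 0.12 with quantile normalization and 0.11 with cyclic loess. Extracellular matrix genes rose (0.13, adjusted p = 0.0454, 1 of 33 higher and 1 lower adjusted over the list alone), and P4ha1, a collagen prolyl hydroxylase gene, went the other way (-0.80). With an adjusted p = 0.576 with an estimated correlation, the matrix call also ended without 6-month replicate 1 (adjusted p = 0.177), 6-month replicate 2 (0.0821), 24-month replicate 1 (0.0505), 24-month replicate 2 (0.0677) or 24-month replicate 3 (0.0533). Exocrine pancreas markers, which are digestive enzyme genes such as Cela1 (0.73) and Cela2a (0.99), rose as a list (1.32, adjusted p = 0.0135, none of 14 over all genes or adjusted over the list alone, adjusted p = 0.708 with an estimated correlation), but their mean was 9.57 in 24-month replicate 2 and between 5.96 and 6.37 in the other 5 arrays. Without that array the median was 0.16 and the adjusted p was 0.0735, and without 24-month replicate 3 the median was 2.01.

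Camera called 21 of 41 lists in liver, 12 higher and 9 lower; 14 of the 21 calls held whichever array was left out, and the split was 14 higher and 5 lower both with quantile normalization and with cyclic loess. No list call in any of the 4 tissues held with an estimated correlation. The 20 lists that did not pass included acute phase proteins (adjusted p = 0.636), hepatocyte products (0.478) and p53 targets and senescence genes (0.513). Cdkn2a, a cell cycle inhibitor gene used as a marker of senescent cells, differed by 0.22 (adjusted p = 0.172).

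In quadriceps, the age comparison gave 1 gene. Mettl21c, a lysine methyltransferase gene expressed in muscle, fell by 0.94 on the log2 scale (1.92-fold lower, SE 0.08), from 9.44 ± 0.11 to 8.50 ± 0.07 (SD, n = 3 per age, limma, adjusted p = 0.0303), with all 3 arrays at 24 months below all 3 at 6 months. The next genes by p did not pass: Cyp4f39 (0.70, adjusted p = 0.0811), Jchain (0.64, adjusted p = 0.163), Sh3rf2 (0.60), Pkp2 (0.57, adjusted p = 0.111) and Prc1 (0.51, adjusted p = 0.186) had higher means, and Pim1 (-0.83, adjusted p = 0.0906), Mfsd4b3-ps (-0.60), the iron exporter gene Slc40a1 (-0.59, adjusted p = 0.0811) and the insulin receptor substrate gene Irs1 (-0.59, adjusted p = 0.101) lower ones. At an unadjusted p under 0.05 there were 1406 of 19928 genes, where 996 would be expected by chance. Mettl21c did not pass without 6-month replicate 1 (adjusted p = 0.145), replicate 2 (0.263) or replicate 3 (0.0869), nor without 24-month replicate 1 (0.0811), replicate 2 (0.305) or replicate 3 (0.172), so the count was then 0 each time, with 1096 to 1583 genes at an unadjusted p under 0.05.

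Gene lists in quadriceps mostly moved down, by small amounts and with no member past over all genes. Heat shock genes fell (median -0.18, adjusted p = 0.000226, 1 of 20 lower adjusted over the list alone), with Dnaja1 at -0.38, Chordc1 at -0.37 and Hsph1 at -0.36. For this list adjusted p = 0.773 with an estimated correlation. The inducible chaperone gene Hspa1a stood at 10.10 in 6-month replicate 3 and between 7.44 and 7.79 in the other arrays, and without that array the list had a median of -0.02 and an adjusted p of 0.275. Without 6-month replicate 1 the median was -0.27. Oxidative phosphorylation genes fell (-0.05, adjusted p = 0.00164, none of 72 adjusted over the list alone, Ndufb2 -0.40), with adjusted p = 0.889 with an estimated correlation. The median was 0.01 without 24-month replicate 1 (adjusted p = 0.980), and -0.03 without 6-month replicate 3 (0.0672), -0.08 without 24-month replicate 2 and -0.08 without 24-month replicate 3. Antioxidant genes fell (-0.02, adjusted p = 0.0437, 1 of 23 lower adjusted over the list alone), with the glutathione synthesis gene Gclm at -0.49, the haem oxygenase gene Hmox1 at -0.48 and Gclc at -0.35. The list had adjusted p = 0.750 with an estimated correlation. That call ended without 6-month replicate 1 (adjusted p = 0.0933), 6-month replicate 2 (0.0971), 24-month replicate 2 (0.119) or 24-month replicate 3 (median -0.0067, 0.157), and the median was -0.05 without 24-month replicate 1 and -0.01 with quantile normalization.

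Fibroblast markers (median -0.07, adjusted p = 0.0353, Col1a2 -0.27) and extracellular matrix genes (-0.05, adjusted p = 0.0420, Col3a1 -0.18) fell in quadriceps, with no member lower adjusted over the list alone. They had adjusted p = 0.782 and adjusted p = 0.773 with an estimated correlation. The fibroblast call ended without 6-month replicate 1 (adjusted p = 0.409) or 24-month replicate 3 (median -0.0033, 0.370), and the matrix call without 6-month replicate 1 (0.200), 6-month replicate 3 (0.0672), 24-month replicate 2 (0.0811) or 24-month replicate 3 (median -0.02, 0.395). Their medians were -0.11 and -0.09 without 6-month replicate 2 and -0.14 and -0.10 without 24-month replicate 1. Mitochondrial biogenesis regulators (-0.07, adjusted p = 0.0353, Tfb1m -0.23) and PPAR targets (-0.09, adjusted p = 0.0420, Angptl4 -0.28) fell, again with none adjusted over the list alone, and with adjusted p = 0.750 and adjusted p = 0.773 with an estimated correlation. The former did not pass without 6-month replicate 3 (median -0.05, adjusted p = 0.111), 24-month replicate 1 (median -0.04, 0.168) or 24-month replicate 2 (0.0525), and the latter without 6-month replicate 2 (0.0745), 6-month replicate 3 (0.192), 24-month replicate 2 (0.192) or 24-month replicate 3 (0.157). The PPAR median was -0.20 without 6-month replicate 1 and -0.18 without 24-month replicate 1. Complement genes of innate immunity (0.06, adjusted p = 0.0420, C4b 0.49) and erythroid markers (0.12, adjusted p = 0.0420, Slc4a1 0.29) rose, with none adjusted over the list alone, and with adjusted p = 0.811 and adjusted p = 0.773 with an estimated correlation. Beside complement, which is largely made in liver, the liver transcripts Alb and Apoa1 stood at 11.91 and 9.30 in 24-month replicate 1, between 7.58 and 10.45 and between 6.64 and 7.55 in the other arrays. Complement did not pass without 6-month replicate 3 (median 0.02, adjusted p = 0.192) or 24-month replicate 1 (median 0.03, 0.980). Its median was 0.09 without 6-month replicate 2 or 24-month replicate 2 and 0.11 without 24-month replicate 3. Erythroid markers did not pass without 6-month replicate 2 (0.0879), 6-month replicate 3 (0.104) or 24-month replicate 1 (median 0.05, 0.690). Their median was 0.22 without dim genes.

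Camera called 9 of 37 lists in quadriceps, 2 higher and 7 lower, and none of these calls held whichever array was left out. Heat shock genes were the only list past the threshold after quantile normalization, and heat shock and oxidative phosphorylation after cyclic loess. Lists that did not pass included muscle atrophy genes (adjusted p = 0.0772), genes of denervation and the neuromuscular junction (0.330) and senescence genes (0.455), and Cdkn2a differed by 0.14 (0.742).

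In heart, 2 genes rose with age. Amtn, which encodes amelotin, a protein known from tooth enamel, rose 1.92-fold, from 5.09 ± 0.13 to 6.03 ± 0.14 (SD, n = 4 per age, limma, adjusted p = 0.0281). Prkcq, which encodes protein kinase C theta, rose 1.65-fold, from 6.92 ± 0.15 to 7.65 ± 0.03 (adjusted p = 0.0348). Both were higher in all 4 arrays at 24 months than in any at 6 months, which chance gives for 2.86% of all genes but which a choice by small p favours. Differences that did not pass were Cyp2b10 (1.10), Csprs (1.06) and the amylase gene Amy1 (0.55), each at an adjusted p of 0.0634, and lower means of Mup-ps21 (-0.71, adjusted p = 0.103), the amino acid transporter gene Slc38a1 (-0.55), Rrad (-0.48, adjusted p = 0.0749), Sema6a (-0.47) and the imprinted gene Peg3 (-0.40, adjusted p = 0.0819). Beside Mup-ps21, a pseudogene of the liver's major urinary proteins, the liver transcript Alb stood at 7.84, 9.54, 5.96 and 6.42 in 6-month replicates 1 to 4 and between 4.73 and 5.37 at 24 months. Of 30063 genes, 1800 had an unadjusted p under 0.05, where 1503 would be expected by chance. Without 6-month replicate 1, 6-month replicate 3 or 24-month replicate 2, 3 or 4 limma called 0 genes (1538 to 2824 at an unadjusted p under 0.05), without 24-month replicate 1 it called 1, and without 6-month replicate 2 or 4 it called 3 or 5. Quantile normalization gave 2 higher and 2 lower genes, and cyclic loess 2 higher and 1 lower.

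Atrial muscle markers fell in heart as a list (median -0.20, camera, adjusted p = 7.73e-05). Of 15 members 13 were lower, none passed over all genes and 1, Peg3, fell adjusted over the list alone. The list had adjusted p = 0.548 with an estimated correlation. Peg3, an imprinted gene, was also lower in liver, quadriceps and gastrocnemius (-0.69, -0.87 and -0.63), so its fall was not confined to heart. Nppa, which encodes atrial natriuretic peptide, went from 12.70 ± 0.20 to 11.66 ± 1.15, Bmp10, a growth factor gene of atrial muscle, differed by -1.73, and Peg3 and Nr2f2 by -0.40 and -0.11. The list mean was 7.47, 8.66, 8.25 and 7.59 in 24-month replicates 1 to 4 and ranged from 8.11 to 8.83 over the 6-month arrays. It thus varied between hearts of one age. The atrial transcript Myl7 stood at 6.34, 10.47, 8.95 and 7.07 in 24-month replicates 1 to 4, against 8.53 to 10.41 at 6 months. Sln, another, ranged from 6.82 to 11.33 at 24 months and from 9.36 to 11.25 at 6 months. The median difference was -0.12 without 6-month replicate 3, -0.32 without 6-month replicate 4 and -0.41 without 24-month replicate 2.

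Extracellular matrix genes fell in heart (median -0.06, adjusted p = 0.000140), with Col3a1 at -0.21, Sparc at -0.18 and Col4a1 at -0.14, and fibroblast markers fell too (-0.04, adjusted p = 0.00413), both with adjusted p = 0.548 with an estimated correlation. No member of either list passed over all genes or adjusted over the list alone. Both calls moved with the atrial markers: with the atrial list mean as a covariate, chosen after seeing the data, the medians were 0.01 and 0.01 and the adjusted p 0.337 and 0.469. The matrix median was -0.09 without 6-month replicate 4 and -0.02 without 24-month replicate 1. The fibroblast median was -0.02 without 6-month replicate 3, -0.08 without 6-month replicate 4 and -0.07 without 24-month replicate 2. Over all alternatives the adjusted p of these lists ran from 3.79e-10 and 2.15e-05 up to 0.569 for each. Amtn and Prkcq lost their calls with it (adjusted p = 0.194 each, 0 genes called by limma, 1732 at an unadjusted p under 0.05), while their differences hardly moved and their standard errors grew: Amtn differed by 0.94 (SE 0.08) without and 0.88 (SE 0.10) with the covariate, and Prkcq by 0.72 (SE 0.07) and 0.76 (SE 0.09). The covariate also ended the calls of heat shock genes (median -0.02, 0.0784), cardiac hypertrophy genes (-0.0039, 0.252), skeletal muscle genes (-0.0042, 0.318) and MHC class I genes (0.254), whose median hardly moved (0.06). With all arrays and no covariate these 3 lists fell and MHC class I rose: heat shock by a median of -0.07 (adjusted p = 0.00790), hypertrophy -0.02 (0.0147, Nppb -0.50), skeletal muscle -0.02 (0.0230) and MHC class I 0.07 (0.0229), with none past over all genes or adjusted over the list alone. For each of these 4 lists adjusted p = 0.548 with an estimated correlation. Hspa1a stood at 7.05 in 6-month replicate 3 and between 5.86 and 6.36 in the other heart arrays. Heat shock did not pass without 6-month replicate 3 (median -0.01, adjusted p = 0.133) or 24-month replicate 1 (0.0698), nor did hypertrophy without 6-month replicate 3 (0.0913), 24-month replicate 1 (0.0951) or 24-month replicate 3 (0.191). The hypertrophy median turned positive without 6-month replicate 3 (0.00083) or 24-month replicate 3 (0.02). It was -0.04, -0.07 and -0.03 without 6-month replicate 1, 24-month replicate 2 and 24-month replicate 4. Skeletal muscle did not pass without 6-month replicate 3 (adjusted p = 0.0558), 6-month replicate 4 (0.0810), 24-month replicate 3 (0.0539) or 24-month replicate 4 (0.311), nor MHC class I without 6-month replicate 3 (0.120), 6-month replicate 4 (0.215), 24-month replicate 1 (median 0.04, 0.139) or 24-month replicate 4 (0.110). The skeletal muscle median turned positive without 24-month replicate 4 (0.01). It was -0.05, -0.0083, -0.04 and -0.05 without 6-month replicates 1 and 4 and 24-month replicates 1 and 2, -0.04 with quantile normalization and -0.03 with cyclic loess. The other 8 lists called in heart besides the atrial markers kept their calls with the covariate: tricarboxylic acid cycle (median -0.06, adjusted p = 0.000344), PPAR-driven fasting (-0.09, 1.73e-05), clock (0.16, 0.0491), MHC class II (0.13, 0.000393), chemokine (0.10, 1.23e-05), antioxidant (0.06, 0.00195), macrophage (0.11, 1.87e-06) and endothelial genes (-0.02, 0.0380).

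Antioxidant genes rose in heart (median 0.05, adjusted p = 0.000473): 20 of 22 members were higher, with Hmox1 at 0.36, the quinone reductase gene Nqo1 at 0.27 and Srxn1 at 0.21. None passed over all genes or adjusted over the list alone. These genes had adjusted p = 0.234 with an estimated correlation. PPAR-driven fasting genes fell (-0.06, adjusted p = 0.000473, and adjusted p = 0.548 with an estimated correlation), none of 16 over all genes, 3 lower and 1 higher adjusted over the list alone: the lipase inhibitor gene Angptl4 at -0.54 and the lipid droplet gene Plin2 at -0.23 against the ketone body enzyme gene Bdh1 at 0.45. Circadian clock genes rose on balance (0.15, adjusted p = 0.00446, and adjusted p = 0.548 with an estimated correlation), none of 17 over all genes, 10 higher and 3 lower adjusted over the list alone, with Dbp at 0.82 and Per3 at 0.28 against Arntl at -0.55, and did not pass without 24-month replicate 4 (adjusted p = 0.102). Tricarboxylic acid cycle genes fell (-0.05, adjusted p = 0.00790, and adjusted p = 0.548 with an estimated correlation), none over all genes or adjusted over the list alone, but not without 24-month replicate 2 (adjusted p = 0.136).

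Some immune lists rose slightly in heart, with no member past over all genes. The interferon, complement, B and plasma cell, T and NK cell and neutrophil lists were not called. Chemokines and cytokines rose (median 0.07, adjusted p = 0.00812, 1 of 28 higher adjusted over the list alone, Ccl11 0.55, Ccl6 0.28, adjusted p = 0.548 with an estimated correlation), but not without 6-month replicate 4 (adjusted p = 0.0764) or 24-month replicate 2 (median 0.03, 0.447). MHC class II genes rose (0.08, adjusted p = 0.0228, none adjusted over the list alone, adjusted p = 0.548 with an estimated correlation), but not without 6-month replicate 4 (adjusted p = 0.287), 24-month replicate 2 (median 0.04, 0.293) or 24-month replicate 4 (0.0533). Macrophage markers rose (0.06, adjusted p = 0.0312, none of 30 adjusted over the list alone, adjusted p = 0.799 with an estimated correlation), but not without 6-month replicate 1 (adjusted p = 0.0757), 6-month replicate 4 (0.530), 24-month replicate 2 (median 0.02, 0.539) or 24-month replicate 3 (0.0705). Endothelial markers fell (-0.04, adjusted p = 0.0228, 2 of 22 lower adjusted over the list alone, adjusted p = 0.548 with an estimated correlation), with the vessel receptor genes Aplnr at -0.60 and Tek at -0.28, but not without 6-month replicate 2 (median -0.02, adjusted p = 0.286), 24-month replicate 1 (0.109) or 24-month replicate 2 (0.0689). Camera called 15 of 36 lists in heart, 6 higher and 9 lower, and 5 of the calls held whichever array was left out. Senescence genes did not pass (0.750), and Cdkn1a (0.34, adjusted p = 0.915) and Cdkn2a (0.15, adjusted p = 0.586) did not either.

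In gastrocnemius, 3 genes rose with age. Amy1, an amylase gene, rose 1.68-fold, from 8.14 ± 0.11 to 8.89 ± 0.14 (SD, n = 4 per age, limma, adjusted p = 0.0461). Aldh1a1, which encodes a retinaldehyde dehydrogenase, rose 1.43-fold, from 10.02 ± 0.04 to 10.53 ± 0.07 (adjusted p = 0.0313), and the predicted gene Gm24838, named after its values were seen, rose by 0.57 (adjusted p = 0.0227). In all 3 genes the 4 arrays of each age did not overlap. Differences that did not pass were higher means of Amy2b (0.60, adjusted p = 0.0633), the matrix gene Efemp1 (0.47, adjusted p = 0.0510) and the macrophage mannose receptor gene Mrc1 (0.41), and lower means of AY036118 (-0.52, adjusted p = 0.0633), Mettl21e (-0.44), C2cd2 (-0.43), Mrm2 (-0.42) and Rnu2-10 (-0.41), each of the last 4 at 0.0734. Of 30063 genes, 4958 had an unadjusted p under 0.05, 2237 higher and 2721 lower, where 1503 would be expected by chance. Limma called 0 genes without 6-month replicate 1, 2 or 3 or 24-month replicate 2 or 4 (3478 to 4722 at an unadjusted p under 0.05), 70 without 6-month replicate 4, 5 without 24-month replicate 1 and 16 without 24-month replicate 3. The age difference followed expression level across genes (rho -0.34), with a median of 0.06 among dim genes and -0.08 among bright ones. Against the mean of the 6-month arrays rho was -0.328, -0.363 and -0.323 in 24-month replicates 1, 2 and 4 but 0.0541 in replicate 3, which had a higher mean Pearson r with the 6-month arrays (0.996) than with its own group (0.995). The interquartile range lay between 2.44 and 2.47 in the 6-month arrays and at 2.39 in 24-month replicates 1, 2 and 4, with 2.46 in replicate 3.

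Lists of energy metabolism and of fast-twitch fibre genes fell in gastrocnemius, with no member past over all genes. Of 71 oxidative phosphorylation genes 60 were lower (median -0.14, camera, adjusted p = 2.83e-09, none adjusted over the list alone), with Uqcr11 at -0.37, Atp5e at -0.37 and Uqcrc1 at -0.32. This list gave adjusted p = 0.645 with an estimated correlation. Fast-twitch fibre genes fell (-0.11, adjusted p = 9.50e-06, 7 of 20 lower adjusted over the list alone), with the glycolytic mutase gene Pgam2 at -0.29, Gpd1 at -0.27 and Myoz1 at -0.19, while the myosin gene Myh4 stood between 13.55 and 13.60 at 6 months and between 13.55 and 13.62 at 24 months. For this list adjusted p = 0.400 with an estimated correlation. Glycolysis genes fell (-0.12, adjusted p = 0.00126, 6 of 18 lower adjusted over the list alone), with Tpi1 at -0.17 and Pkm at -0.16. The list had adjusted p = 0.322 with an estimated correlation. Polyamine and creatine genes fell (-0.13, adjusted p = 0.0131, 3 of 15 lower adjusted over the list alone), with the spermine oxidase gene Smox at -0.56 and the muscle creatine kinase gene Ckm at -0.18, and antioxidant genes fell (-0.10, adjusted p = 0.00951, none of 22 adjusted over the list alone), with the superoxide dismutase gene Sod1 at -0.24. For both adjusted p = 0.228 with an estimated correlation. Fatty acid oxidation genes fell (-0.11, adjusted p = 0.0147, none of 25 adjusted over the list alone, adjusted p = 0.702 with an estimated correlation), but not without 6-month replicate 3 (median -0.04, adjusted p = 0.268) or 24-month replicate 4 (-0.02, 0.850). Their median was -0.17 without 6-month replicate 4 and -0.16 without 24-month replicate 3. Lipogenesis genes fell (-0.04, adjusted p = 0.0496), with 1 of 21 higher adjusted over the list alone, the desaturase gene Scd1 (0.61), against Lpin1 (-0.34) and Acacb (-0.28). These genes had adjusted p = 0.645 with an estimated correlation. That call ended without 6-month replicate 3 (adjusted p = 0.334), 24-month replicate 1 (median -0.07, 0.0969) or 24-month replicate 4 (0.287). The median was -0.07, -0.07, -0.06 and -0.09 without 6-month replicates 1 and 2 and 24-month replicates 2 and 3. The median of oxidative phosphorylation was -0.09 without 6-month replicate 3. Without 24-month replicate 4 those of polyamine and antioxidant genes were -0.08 and -0.05.

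Several lists of immune genes rose in gastrocnemius, with no member past over all genes, while neutrophil markers were not called. Of 30 macrophage markers 29 were higher (median 0.13, adjusted p = 1.24e-06, 3 higher adjusted over the list alone), with Cd163 at 0.50, Mrc1 at 0.41 and Vsig4 at 0.37, all of tissue-resident macrophages. This list gave adjusted p = 0.400 with an estimated correlation. All 17 B and plasma cell markers were higher (0.24, adjusted p = 0.000759, none adjusted over the list alone), with Ighm at 0.70, and adjusted p = 0.645 with an estimated correlation, but the list did not pass without 24-month replicate 1 (median 0.04, adjusted p = 0.125). MHC class II genes (0.23, adjusted p = 0.0229, Ctss 0.45) and T and NK cell markers (0.10, adjusted p = 0.0147) rose with none adjusted over the list alone, and for both adjusted p = 0.654 with an estimated correlation. The former did not pass without 6-month replicate 1 (adjusted p = 0.0535), 6-month replicate 4 (0.0744) or 24-month replicate 1 (median 0.04, 0.383), nor the latter without 6-month replicate 4 (0.0513) or 24-month replicate 1 (median 0.02, 0.455). Without 24-month replicate 1 the macrophage median was 0.08. Without 24-month replicate 3 the medians of the B cell and T and NK cell lists were 0.37 and 0.17. Complement genes (0.06, adjusted p = 0.0131, 1 of 23 higher adjusted over the list alone, C7 0.70) and chemokines (0.09, adjusted p = 0.0215, none of 28 adjusted over the list alone, Cxcl13 1.03) rose, with adjusted p = 0.400 and adjusted p = 0.652 with an estimated correlation. Neither passed without 24-month replicate 1 (0.0539 and 0.583, chemokine median 0.06). The complement median was 0.09 without 6-month replicate 3 and 0.10 without 24-month replicate 3. The chemokine median 0.06 with quantile normalization and 0.14 without dim genes. Interferon response genes fell (-0.04, adjusted p = 0.0398, none of 33 adjusted over the list alone, adjusted p = 0.654 with an estimated correlation), but not without 6-month replicate 1 (adjusted p = 0.0640), 6-month replicate 4 (0.187), 24-month replicate 2 (median -0.0075, 0.321) or 24-month replicate 4 (0.174). The interferon median was -0.06 without 24-month replicate 3, -0.07 with quantile normalization and -0.06 with cyclic loess.

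Vessel, matrix and nerve sheath genes fell in gastrocnemius, again with no member past over all genes. Endothelial markers fell (median -0.22, adjusted p = 8.72e-07, 7 of 22 lower adjusted over the list alone), with Esam at -0.30, Robo4 at -0.26 and Vwf at -0.18. For this list adjusted p = 0.400 with an estimated correlation. Extracellular matrix genes fell (-0.09, adjusted p = 0.00136, 7 of 33 lower and 1 higher adjusted over the list alone), with the fibrillar collagen genes Col1a1 at -0.51 and Col3a1 at -0.37, and fibroblast markers fell (-0.06, adjusted p = 0.0229, 4 of 22 lower adjusted over the list alone), both with adjusted p = 0.645 with an estimated correlation. The fibroblast call ended without 6-month replicate 1 (adjusted p = 0.0535), 6-month replicate 3 (median -0.03, 0.0815), 24-month replicate 2 (-0.01, 0.108) or 24-month replicate 4 (-0.03, 0.141). Without 24-month replicate 3 the fibroblast and matrix medians were -0.09 and -0.15, and without 6-month replicate 3 the matrix median was -0.04. Markers of satellite cells, the stem cells of muscle, fell (-0.12, adjusted p = 0.000299, none of 16 adjusted over the list alone), with Dag1 at -0.18 and Itga7 at -0.17, and Schwann cell markers fell (-0.07, adjusted p = 0.0147, 4 of 18 lower and 1 higher adjusted over the list alone), with Pmp22 at -0.32 and Mbp at -0.24. For both adjusted p = 0.228 with an estimated correlation. Endoplasmic reticulum stress genes rose (0.05, adjusted p = 0.0147, 5 of 26 higher and 1 lower adjusted over the list alone), with the chaperone genes Hspa5 at 0.38, Canx at 0.30 and Hsp90b1 at 0.28 and adjusted p = 0.400 with an estimated correlation, but not without 24-month replicate 3 (adjusted p = 0.186). Autophagy genes fell (-0.04, adjusted p = 0.0185, 2 of 23 lower adjusted over the list alone, adjusted p = 0.446 with an estimated correlation), but not without 24-month replicate 4 (median -0.01, adjusted p = 0.141), and the median was -0.06 without 6-month replicate 4 and -0.07 without 24-month replicate 3.

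Camera called 21 of 37 lists in gastrocnemius, 7 higher and 14 lower, and 10 of the calls held whichever array was left out. The split was 8 higher and 7 lower with quantile normalization, which ended the calls of glycolysis, antioxidant, polyamine, fatty acid oxidation, lipogenesis, autophagy and fibroblast genes, and 7 higher and 8 lower with cyclic loess. With these 2 settings the medians were -0.08 and -0.09 for oxidative phosphorylation, -0.04 and -0.07 for glycolysis, -0.05 and -0.07 for antioxidant, -0.07 and -0.07 for fatty acid oxidation, -0.02 and -0.02 for autophagy and -0.02 and -0.03 for fibroblast genes. Quantile normalization gave -0.06 for polyamine and cyclic loess -0.06 for fast-twitch genes. Leaving out dim genes also ended those of the Schwann cell (median -0.11) and interferon lists. Atrophy genes (adjusted p = 0.0558), denervation genes (0.758) and senescence genes (0.319) did not pass, and Cdkn1a (-0.10, adjusted p = 0.843) and Cdkn2a (-0.03, adjusted p = 0.785) did not either.

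**Figure D2:**
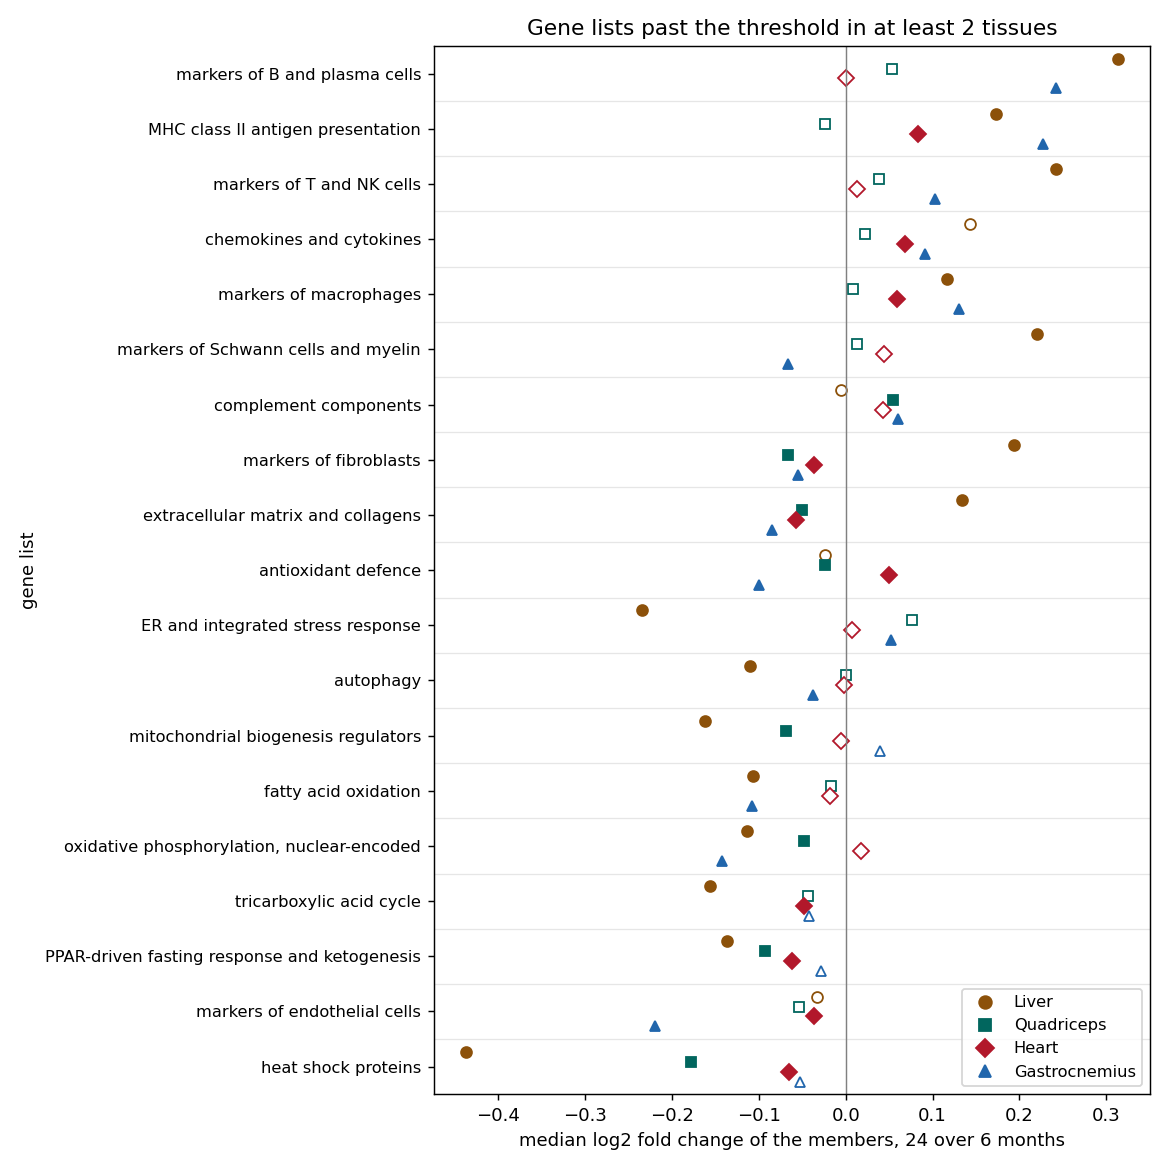
Median log2 difference between 24 and 6 months over the members of each gene list (horizontal axis) for the lists past the threshold in at least 2 tissues, with 1 marker per tissue, filled where camera gave an adjusted p under 0.05 and open where it did not. Heat shock genes lie at -0.44 in liver and -0.18 in quadriceps, and fibroblast markers lie at 0.19 in liver and below 0 in the other tissues.

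The age effects of tissues on the same array type were compared by the difference of their log2 differences. Between liver and quadriceps 3 genes passed: Mettl21c, with 0.07 in liver and -0.94 in quadriceps (difference 1.02, adjusted p = 0.0201), Sel1l3, with -0.92 and 0.16 (-1.08, adjusted p = 0.0261), and Il1a, with -0.87 and 0.28 (-1.16, adjusted p = 0.0261). Noct (1.02) and Cdh1 (-1.24) did not pass (adjusted p = 0.0555). At an unadjusted p under 0.05 there were 3948 genes. Limma called 48, 3 and 2 genes without liver 6-month replicates 1, 2 and 3, 7, 3 and 1462 without liver 24-month replicates 1, 2 and 3, 10, 0 and 1 without the quadriceps 6-month replicates and 0, 0 and 1 without its 24-month replicates, and quantile normalization gave 3 higher and 2 lower differences against 1 and 2. Mettl21c did not pass without quadriceps 6-month replicate 2 (adjusted p = 0.0808), 24-month replicate 1 (0.0598) or 24-month replicate 2 (0.106), and Sel1l3 and Il1a did not in 7 and 6 of the 12 fits without 1 array.

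Between heart and gastrocnemius the age effect differed for 179 genes, 147 of them more positive and 32 more negative in heart. Amtn (0.94 in heart, difference 0.93, adjusted p = 0.00155) and Prkcq (difference 0.72, 0.0118) led, followed by the ubiquitin-conjugating enzyme gene Cdc34 (0.14 in heart, -0.43 in gastrocnemius), the lysosome positioning gene Borcs6 (0.31 and -0.39) and C2cd2 (0.14 and -0.43), each at an adjusted p of 0.0122. These 5 genes passed whichever array was left out. With the replicate number as a block 4 of them did not pass. Prkcq, Cdc34 and C2cd2 then had an adjusted p of 0.0559 (limma) and Borcs6 of 0.0577. Amtn passed in every alternative (adjusted p at most 0.0369). Of the 179, 167 had opposite signs in the 2 tissues and 4 were called in either tissue alone. Another 92 of the 179, counted without regard to these, carry symbols of kinds that the naming rule left out. Such kinds are numbered predicted genes, some small RNAs and olfactory receptor genes, among others. The count was 22, 54, 106 and 118 without heart 6-month replicates 1 to 4, 33, 53, 33 and 209 without its 24-month replicates, 318, 27, 28 and 170 without the gastrocnemius 6-month replicates and 63, 36, 547 and 64 without its 24-month replicates. Quantile normalization gave 69 more positive and 44 more negative differences, against 147 and 32. The age difference followed expression level in gastrocnemius (rho -0.34) but hardly in heart (rho -0.05). Single heart arrays did show trends, in opposite directions. Against the mean of the 6-month arrays rho was -0.200, -0.212, 0.0947 and 0.225 in 24-month heart replicates 1 to 4. For each 6-month heart array against the others it lay between -0.116 and 0.208. How far such trends make up the differences between these tissues was not tested. At an unadjusted p under 0.05 there were 4135 genes.

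No gene was called with limma in the same direction in any of the 6 pairs of tissues. At an unadjusted p under 0.05 in both tissues, 1471 genes were shared in direction when summed over the pairs, where 1158 would be expected from the number of such genes in each tissue, and at an unadjusted p under 0.01 there were 198 against 129. At the latter threshold both leg muscles shared 20 higher genes (3.82 expected, Fisher's exact test, one-sided, adjusted p = 1.96e-08) and 21 lower genes (4.70 expected, 5.79e-08). Liver and quadriceps shared 27 higher (13.2 expected, 0.000721) and 25 lower genes (9.05, adjusted p = 1.45e-05), quadriceps and heart 6 (1.72, adjusted p = 0.0132) and 5 (0.893, adjusted p = 0.00408), and heart and gastrocnemius 19 higher (7.19, adjusted p = 0.000401) and 8 lower (5.75, adjusted p = 0.263). Liver and heart shared 18 higher genes where 13.5 would be expected and 10 lower where 6.25 would be. Liver and gastrocnemius shared 15 higher genes where 30.1 would be expected and 24 lower where 32.9 would be. Fisher's exact test counts genes as independent, which they are not, so the p-values of these overlaps can be too small. The labels do not say whether tissues share animals, so genes shared for that reason cannot be set apart. Pearson r of the age differences across genes, which are not independent replicates, lay between -0.07 for heart and gastrocnemius and 0.17 for liver with quadriceps or heart. The 2 array types came as separate tables, so no level was compared between them.

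**Figure D3:**
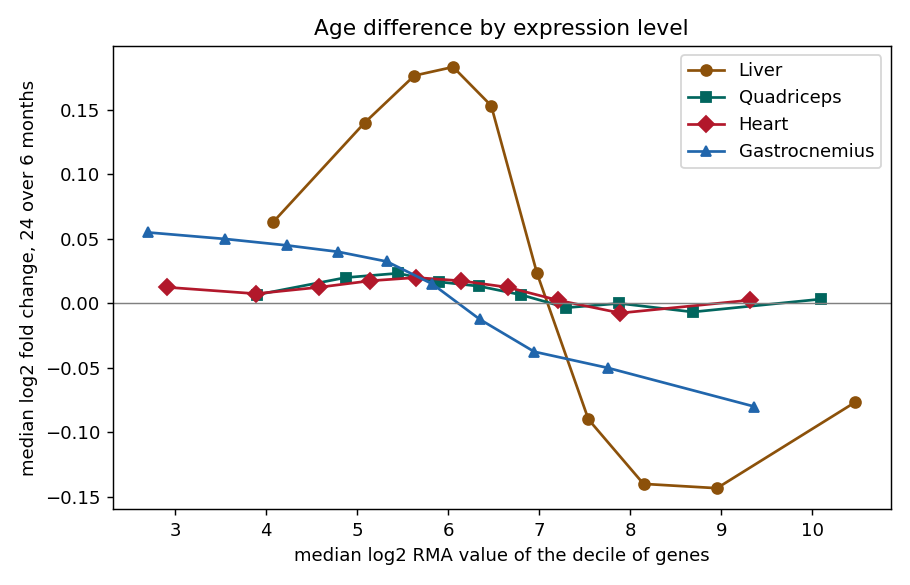
Median log2 difference between 24 and 6 months (vertical axis) in each of 10 equal classes of genes ordered by mean log2 expression (horizontal axis), with 1 line per tissue. Liver runs from 0.18 in class 4 to -0.14 in classes 8 and 9, gastrocnemius reaches -0.08 among bright genes, and quadriceps and heart stay closer to 0.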

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

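The tests of the trend in single liver arrays, of pancreas markers, of atrial markers and of clock genes were chosen only after the results were seen, as was cyclic loess normalization; the other tests here were planned.

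In liver, genes of high expression were lower and genes of low expression higher at 24 months, and the energy lists lay among the former. For the sex-biased lists 2 of 2 medians lay outside the middle 95% of matched random lists, and for the immune cell lists 4 of 4 did. These medians thus lay beyond what an array-wide trend with expression level gives to genes drawn independently. Lists whose genes vary together can leave this band without an effect of age, which the test cannot tell apart. For the 3 liver energy lists 0 of 3 lay outside: after cyclic loess the median of oxidative phosphorylation went from -0.11 (quartiles -0.20 and -0.04) to -0.05 (-0.11 and 0.02) and that of fatty acid oxidation from -0.11 (-0.20 and -0.01) to -0.05 (-0.12 and 0.02), which ended both calls with no cause tested beyond the smaller median (adjusted p = 0.0671 and 0.189; over all alternatives 1.21e-06 to 0.437 and 0.00401 to 0.576), while the tricarboxylic acid cycle stayed past the threshold at -0.06 (0.0287), so a trend may account for the first 2 and part of the third. In gastrocnemius 1 of 3 energy and fibre lists lay outside (oxidative phosphorylation, percentile 0.04), which does not decide for the 3 as a set; after cyclic loess oxidative phosphorylation, glycolysis and fast-twitch genes stayed past the threshold at smaller medians (-0.09, -0.07 and -0.06, adjusted p = 0.000835, 0.0414 and 0.00764), so a trend may account for part of these falls, although 24-month replicate 3 did not show it (rho 0.0541, -0.363 to -0.323 in the others). The liver trend was present in every 24-month array, with a weakest Spearman rho of -0.215 across genes (replicate 3, with -0.476 and -0.454 in the others) against -0.0549 to 0.0437 for each 6-month array against the others, so it is no property of 1 array; whether it comes from the normalization, RNA composition or age stays open.

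Transcripts typical of neighbouring tissue varied between samples of one tissue. In liver, 14 of 14 exocrine pancreas markers were highest in 24-month replicate 2, with Ctrb1 at 11.15, Cela2a at 9.01 and Prss2 at 8.47; 2 of the 14 lie above the median gene in 6-month liver and 0 are in another list, so pancreas tissue taken with that sample is a candidate source, and an age effect was not seen without it (median 0.16). In heart, the atrial list means of 24-month replicates 1 and 4 (7.47 and 7.59) lay below every 6-month array. Those of replicates 2 and 3 (8.66 and 8.25) did not. Myl7 parted the same way, at 6.34 and 7.07 against 10.47 and 8.95, with 8.53 to 10.41 at 6 months. With 2 of 4 arrays below, no loss of atrial transcripts that parts all old from all young hearts was seen. A smaller loss common to old hearts cannot be judged by this, because the list mean varied between hearts of one age. Within ages the 15 atrial markers varied together (median pairwise r 0.563, percentile 100 of matched random lists), although 14 lie above the median gene in 6-month heart and 2 are in another list, which is consistent with a share of atrial tissue that differed between samples. With that share as a covariate 0 genes were called in heart, but Amtn and Prkcq still differed by 0.88 and 0.76 (0.94 and 0.72 without it), so the lost calls do not bear on atrial share as their source, and for the atrial markers an age effect on atrial muscle and a difference in dissection both stay open.

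The clock list, tested for a move in one direction, passed in heart only (adjusted p = 0.327, 0.331 and 0.592 in liver, quadriceps and gastrocnemius), and adjusted over the list alone 1 gene was higher and 2 lower in liver, 1 lower in quadriceps, 10 higher and 3 lower in heart and 1 lower in gastrocnemius. By sign alone, in liver 13, in quadriceps 13 and in heart 14 of the 14 measured genes moved as a change of phase predicts, the lowest of these counts being 13, and 11 did in gastrocnemius. A different phase of the clock at collection is therefore a candidate explanation; Dbp differed by 0.50, 0.39, 0.82 and 0.17 and Arntl by -0.68, -0.35, -0.55 and -0.20 in liver, quadriceps, heart and gastrocnemius. The labels used here give no hour of collection, and an effect of age on the clock itself was not tested and stays open.

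Other splits of the same arrays were counted, and each number of splits as large includes the real one. With 3 arrays against 3 the 10 splits are too few for a share under 0.05: liver gave 65 genes against 0 in the highest other split and 21 lists against 21, and quadriceps 1 gene against 0 and 9 lists against 18, with 1, 2, 1 and 5 splits as large. Among the 35 splits in heart, 1 split was as large for the 2 genes (highest other 1) and for the 15 lists (highest other 10). In gastrocnemius 1 split was as large for the 3 genes (highest other 0) and 5 for the 21 lists (highest other 22). A share of 1 in 35 is the lowest these splits can give, and the shares were not adjusted over the tests. For the heart genes and lists and the gastrocnemius genes it thus argues only weakly against chance. For the gastrocnemius lists chance stays open. Of 100 splits, 3 gave at least as many genes as the 3 of liver against quadriceps: the real one, 1 with 3 and 1 with 270. Apart from the real one, these splits kept the liver arrays parted by age and mixed the ages in quadriceps. They thus hold the liver age difference, and a share counted with them cannot decide on chance. The highest of the 81 splits that mix the ages in both tissues was 1. For heart against gastrocnemius 1 split was as large (179 against 7 in the highest other). The 93 splits that mix the ages in both tissues gave at most 1. Mixing the ages adds any age difference to the spread between arrays, which lowers these counts. The share thus argues against the case that neither tissue differs with age. It cannot decide whether the age effect differs between the tissues.

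Single arrays lay far from the other 3 of their group in 14 of 262 groups of values, where chance gives about 13.1. In heart at 24 months these were Rrad in replicate 3 (9.69; others 9.80 to 9.82), Nqo1 in replicate 4 (9.28; 8.86 to 8.91), Arntl in replicate 2 (7.30; 7.56 to 7.58), Sparc in replicate 3 (9.97; 10.11 to 10.13), Bmp10 in replicate 2 (5.47; 5.05 to 5.12) and Tek in replicate 4 (8.87; 8.75 to 8.76). In gastrocnemius at 24 months they were Atg9a in replicate 1 (8.69; 8.82), C6 in replicate 1 (3.89; 3.71 to 3.73), Hspa5 in replicate 3 (9.25; 9.17 to 9.18) and the interquartile range of replicate 3 (2.46; 2.39). At 6 months they were Ighm in replicate 1 (6.60; 7.19 to 7.30), Ckm in replicate 1 (13.11; 13.18 to 13.19), Dag1 in replicate 3 (9.26; 9.19 to 9.20) and Pmp22 in replicate 3 (9.25; 9.08 to 9.10).

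Age effects that differed between tissues by the test of the difference were 3 genes in liver against quadriceps (Mettl21c 1.02, Sel1l3 -1.08, Il1a -1.16) and 179 in heart against gastrocnemius. Among the latter, genes named in the text were Amtn (0.93), Prkcq (0.72), Cdc34 (0.57), Borcs6 (0.70), C2cd2 (0.57), Cyp2b10 (1.11), Rnu2-10 (0.85), Mrm2 (0.62), AY036118 (0.61) and Mettl21e (0.44) with the more positive effect in heart, and Mup-ps21 (-0.75), Slc38a1 (-0.71), Aldh1a1 (-0.56), Mrc1 (-0.43), Hspa5 (-0.37) and Canx (-0.31) with the more positive effect in gastrocnemius.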

How the results depend on the processing

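The normalization by cyclic loess, the atrial covariate and the count over all 4 tissues were chosen only after the results were seen. Where no reason is given, the cause was not tested. Counts of genes called moved as follows. In liver (65) they were 8 with quantile normalization (4 higher, 4 lower), 2870 with arrays centred on their median, 1819 without dim genes, 0 over every probe set (8725 at an unadjusted p under 0.05), 2243 with an intensity trend, 3625 in the joint fit, 7897 with array weights and 42 at 1.5-fold or more, and 0 to 5073 with 1 array left out; all 65 were also called after centring and with array weights, and 49 with cyclic loess. In quadriceps (1) they were 9 without dim genes, 0 over every probe set (1896 at an unadjusted p under 0.05), 18 with the trend, 15 in the joint fit, 8 with weights and 0 to 0 with 1 array left out. In heart (2) they were 4 with quantile normalization, 1 after centring, 20 without dim genes, 49 over every probe set, 14 with the trend, 25 in the joint fit, 4 with weights, 0 with the atrial covariate and 0 to 5 with 1 array left out. In gastrocnemius (3) they were 1 after centring, 58 without dim genes, 0 over every probe set (8294 at an unadjusted p under 0.05), 9 with the trend, 829 in the joint fit (197 higher, 632 lower), 89 with weights, 1 at 1.5-fold or more and 0 to 70 with 1 array left out. Leaving out dim genes tests fewer genes, and the joint fit has more arrays behind its spread. Lists called with an estimated correlation were 0 in every tissue (0 to 5 at an unadjusted p under 0.05), and with fry 3, 0, 0 and 7 in liver, quadriceps, heart and gastrocnemius; in quadriceps (9) they were 1 with quantile normalization, 3 without dim genes and 2 with cyclic loess. With 1 array left out they were 18 to 23, 4 to 12, 10 to 16 and 15 to 22. Differences between tissues numbered, for liver against quadriceps (3), 159 with the trend, 198 without dim genes, 5 with quantile normalization and 0 to 1462 with 1 array left out, and for heart against gastrocnemius (179), 353 without dim genes, 113 with quantile normalization and 22 to 547 with 1 array left out. Genes shared by 2 tissues (0) were 198 at an unadjusted p under 0.01, 4 without dim genes and 8 over all 4 tissues. Reversed by the direction of the test were the oxidative phosphorylation list in quadriceps without 24-month replicate 1 (median 0.014, -0.083 to 0.014 over the arrays) and Cdkn1a in gastrocnemius without 6-month replicate 3 (0.0050) or 24-month replicate 4 (0.069, -0.30 to 0.069 over the arrays). Medians of called lists also turned sign in heart, with the test still pointing down, for hypertrophy genes without 6-month replicate 3 (0.00083) or 24-month replicate 3 (0.018), skeletal muscle genes without 24-month replicate 4 (0.014), and matrix genes and fibroblast markers with the atrial covariate (0.0080 and 0.011). Of the other comparisons of single genes with an alternative 3496 kept direction and side of the threshold, 379 gained a call and 209 lost one, and of those of lists 602 kept it and 273 lost it. For genes of the tissue differences these counts were 145 kept, 11 gained and 24 lost. The samples share only replicate numbers: deviations of same-numbered arrays had r from -0.22 to 0.30 within a tissue and from -0.11 to 0.19 between tissues, so not every pair is over 0.1 and the numbers were not taken as pairs. In gastrocnemius 3 of 4 same-numbered arrays correlated best with each other (0.129, 0.214 and 0.299; replicate 2 -0.0446), a hint from the data, as against 2 of 3 in liver, 1 of 3 in quadriceps and 0 of 4 in heart. Hspa1a was highest in 6-month replicate 3 in liver, quadriceps and heart. In gastrocnemius that replicate was the highest of the 6-month arrays (6.46), but 24-month replicate 1 lay above it (6.77). With the replicate number as a block the counts were 0 genes in liver, quadriceps, heart and gastrocnemius, 0 and 6 in the 2 tissue differences, and 20, 9, 16 and 20 lists. What signal over background limits was not tested, since no background values were used here.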

Other observations

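The count of genes moving alike in all 4 tissues was chosen only after the results were seen. At an unadjusted p under 0.05 in each tissue, 8 of 18974 genes differed in the same direction in all 4, where 0.451 would be expected from the share of such genes per tissue. Higher at 24 months were Amy1, an amylase gene (0.27, 0.69, 0.55 and 0.75 in liver, quadriceps, heart and gastrocnemius), Jchain, the joining chain of secreted antibodies (0.98, 0.64, 0.23 and 0.17), Acsl6, an acyl-CoA synthetase gene, and Mmp3, a matrix protease gene. Lower were the imprinted gene Peg3 (-0.69, -0.87, -0.40 and -0.63; adjusted p = 0.0493 in liver), Zfp36l1, whose product promotes mRNA decay (-0.33, -0.41, -0.31 and -0.36), the histone gene H1f2 and the small nucleolar RNA Snord14e. With cyclic loess 5 genes did so (0.380 expected), among them Amy1, Peg3 and Snord14e. These genes were picked by their values, so the count describes these samples.

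Liver transcripts were also measured in muscle samples: Alb ranged from 7.58 to 11.91 and Apoa1 from 6.64 to 9.30 over the quadriceps arrays. In heart, Mup20, a major urinary protein gene, stood at 6.56 and 7.69 in 6-month replicates 1 and 2 and between 3.80 and 4.24 at 24 months.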
